A study of Mus musculus with 16 samples.

How the data were processed

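Gene expression was measured in whole lung tissue of C57BL/6 mice aged 6 to 12 weeks, WT or Nrf2 null, 24 h after instillation of PBS or S. pneumoniae at 2.3 µl per g body weight. Each of the 4 groups held 4 arrays, all Affymetrix Mouse Gene 2.1 ST, and groups and replicate numbers were taken from the labels. Total RNA was isolated with miRNeasy kits and turned into labelled sense-strand cDNA, per the labels' protocols. The submitters' processing notes name Affymetrix Expression Console, RMA and Partek, without versions, roles or order. The deposited table holds 1 value per transcript and array on a scale read here as log2, because its values run from 3.14 to 13.93 and the notes name RMA, which gives log2 values; the log base is not stated. The genome build is not given in the sources used here. The table gives no background or detection values, so a low value cannot be told from no signal.

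The table has 31350 transcripts. Of these, 21056 carried an accession that matched 1 gene in the gene table supplied for this work (assembly GRCm38.p6), which was used only for names and for which genes neighbour each other. Where 34 genes had more than 1 transcript, the transcript with the highest mean over the 16 arrays stood for the gene, which left 21022 genes, 18373 of them protein-coding. The other 10294 transcripts, among them 7969 with Ensembl and 570 with GenBank accessions, were not matched and were tested only in an alternative. Genes missing from the table or not matched were not analysed here.

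The values were tested as deposited, without further normalization or filter. Per gene, limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings) fitted a mean for each of the 4 groups over all 16 arrays, with 12 residual degrees of freedom. Contrasts were infected minus PBS in each genotype, Nrf2 null minus WT after each instillate, and the interaction. Tests were two-sided with Benjamini-Hochberg adjustment over the 21022 genes of each contrast, and a gene was called at adjusted p under 0.05; "higher", "rose", "lower" and "fell" refer to such calls for single genes, except where a group or its members are said to lie higher or lower. Errors of fold changes are limma's moderated standard errors, with 4 arrays per group. They rest on a spread per gene shared by the 4 groups, so they do not give the spread of the groups compared. Nfe2l2 and Nqo1 were also compared between the 8 arrays of each genotype with two-sided exact permutation tests.

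Lists of genes for 31 processes, cell types and tissues were written before the data were examined, as were the designs, the naming rule and all but 1 of the alternatives. Of their 459 members, 412 were measured, counting a gene again in each list that holds it. Mmp8 and Mmp9, for example, are in both neutrophil lists, and Cd8b1 is in the T cell and thymocyte lists. Lists that share genes are not independent of each other. Each list was tested in each of the 5 contrasts with camera, which asks whether its genes shift relative to all others, at a preset correlation between genes of 0.01 and with adjustment over 155 tests, and again with a correlation estimated from the data. Of the 73 lists called with the preset correlation, 2 held with the estimated one, NRF2 targets between genotypes after PBS and after infection. Limma's fry was an alternative and called 49: its directional p tests whether a list's genes move, on balance, one way, and its mixed p whether they change in either direction, and neither compares the list with other genes. Counts adjusted over the list alone apply the Benjamini-Hochberg adjustment to the list's members only.

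The genes named were fixed by rule: Nfe2l2 in every comparison; in each comparison of 2 groups the 8 genes with the largest rise and the 8 with the largest fall among those past the threshold whose 2 groups of 4 arrays do not overlap; and in the interaction up to 6 in each direction. The interaction compares 4 groups, so overlap was not considered there. Predicted genes with a Gm number, Rik clones, microRNAs, small nucleolar RNAs and antigen receptor segments were passed over, which concerned Mir130a, Gm3776, Gm3893 and Gm6654. In each list described, up to 4 members with the largest change were named, and members that moved against their list, shared calls and Cpeb1 were named after their values were seen.

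On simulated data with 200 of 21022 genes changed, the test recovered 74% of log2 changes of 0.5 and 99% of changes of 1 between genotypes after PBS, 66% and 95% after infection, and 56% and 92% in the interaction. It called 12, 5 and 12 unchanged genes in these, and 0 of 155 lists when no gene was changed. Genes were simulated independently of each other, so the last value does not show how often lists of correlated genes are called. Each gene also had the same spread in all 4 groups, so neither the recovery nor the calls of unchanged genes reflect groups that spread unequally. Alternatives covered the replicate number as a block, filters on dim genes, a floor, other scalings, array weights, other variance models, thresholds, the treatment of several transcripts per gene, unmatched transcripts, the genes around Nfe2l2, the arrays entering the fit and leaving out each array. Leaving out infected Nrf2 null replicates 1 and 2 together was chosen after seeing the data. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.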

Results

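Whole lung RNA was measured on 16 Affymetrix Mouse Gene 2.1 ST arrays, one per mouse, 24 h after an intratracheal instillation into the left lung. The mice were wild type (WT) or lacked Nfe2l2, the gene of the transcription factor NRF2, which switches on antioxidant and detoxifying genes. Each genotype received either phosphate-buffered saline (PBS) or a suspension of Streptococcus pneumoniae, a bacterium that causes pneumonia, which made 4 groups of 4 arrays. Array medians lay between 5.63 and 5.72 on the log2 scale, and the number of arrays limits the precision of every value. The first principal component held 75.4% of the variance and separated infected from PBS lungs, and the second held 4.39%. Infected Nrf2 null replicates 1, 2 and 4 lay at 20.45, 57.79 and 45.09 on the first component, outside the range of 36.94 to 43.28 of the infected WT arrays.

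The RNA level of the targeted gene, Nfe2l2, was 11.12 and 11.22 (log2 group means, n = 4 arrays each) in PBS and infected WT lungs, and 11.05 and 11.11 in PBS and infected Nrf2 null lungs. Nfe2l2 differed between genotypes by -0.08 ± 0.05 (log2 difference ± SE) in PBS lungs and by -0.11 ± 0.05 in infected lungs, with limma adjusted p = 0.692 and 0.467. Infection changed Nfe2l2 by 0.09 in WT lungs and by 0.07 in Nrf2 null lungs, with adjusted p = 0.133 and 0.309. Over both instillates, the mean was 11.17 in 8 WT arrays and 11.08 in 8 Nrf2 null arrays (difference -0.09, two-sided exact permutation p = 0.0109 over 12870 relabellings). The sources used here do not say which part of the gene the probes cover or which part was deleted, and probes outside the deleted part would check nothing. Nqo1, which encodes a quinone reductase that NRF2 induces, averaged 5.77 in the 8 Nrf2 null arrays, a difference of -2.23 from the 8 WT arrays (exact permutation p = 0.000155, the smallest these relabellings can give).

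The comparison of infected with PBS lungs in WT mice asks how the lung responds to the bacteria within a day. Acod1, whose enzyme makes itaconate in activated macrophages, rose by 5.63 ± 0.57 (log2 fold change ± SE, n = 4 arrays per group, limma adjusted p = 1.53e-06), a 49.5-fold increase. The chemokine genes Ccl3, Cxcl9, Cxcl10 and Ccl4 rose by 5.06 ± 0.63, 5.05 ± 0.61, 4.88 ± 0.47 and 4.73 ± 0.32. Gpr84, a receptor gene of activated myeloid cells, rose by 4.93 ± 0.19, the cytokine gene Tnf by 4.83 ± 0.37 and the acute phase gene Orm2 by 4.64 ± 0.28. The largest falls were in Lrat, which stores retinol as esters (-3.27 ± 0.45), the clock output gene Dbp (-3.14 ± 0.32), the carboxylesterase gene Ces1g (-3.13 ± 0.10) and Mettl7a3 (-3.03 ± 0.39). Fgfr4, a fibroblast growth factor receptor gene, fell by 3.02 ± 0.28, and Abca8a fell by 2.77 ± 0.27. Faim2 fell by 2.65 ± 0.37 and Acoxl fell by 2.63 ± 0.33. The adjusted p of these 16 genes lay between 6.17e-11 and 3.34e-05. Over all 21022 genes, 8134 passed adjusted p under 0.05, 3339 higher and 4795 lower, and of these 1316 changed at least 2-fold. WT PBS replicate 1 held more Acod1 (9.05) than the other WT PBS arrays (5.27 to 5.78), and likewise Cxcl10 (9.16 against 6.35 to 6.62) and Orm2 (6.94 against 5.46 to 5.53). The same array held the most Ccl3 (10.69 against 6.44 to 7.58), Cxcl9 (9.47 against 5.82 to 6.45), Tnf (8.10 against 5.91 to 6.70), Ccl4 and Gpr84. These rises are measured against unequal PBS arrays.

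In Nrf2 null mice the same comparison was again led by Acod1, which rose by 7.16 ± 0.57 (adjusted p = 1.06e-07). Ccl4 rose by 6.10 ± 0.32, Ccl3 by 6.00 ± 0.63, Cxcl10 by 5.96 ± 0.47 and Gpr84 by 5.73 ± 0.19. Cxcl9 followed with 5.37 ± 0.61, Hcar2, a receptor gene for hydroxybutyrate and niacin, with 5.34 ± 0.30 and Tnf with 5.33 ± 0.37. Fgfr4 fell by 2.64 ± 0.28, and Lrat by 2.62 ± 0.45. Acoxl fell by 2.56 ± 0.33 and Scube2 fell by 2.54 ± 0.33. The carbonic anhydrase gene Car3 fell by 2.46 ± 0.43, and Krtap17-1 by 2.42 ± 0.26. The sodium channel gene Scn3a fell by 2.40 ± 0.29 and Stmn2, a neuronal microtubule regulator gene, fell by 2.35 ± 0.48. The adjusted p of these 16 genes reached at most 0.000954, for Stmn2. The SEs use a spread shared by the 4 groups, which can understate the error of the falls. Infected Nrf2 null arrays had SDs of 1.52 for Stmn2, 1.33 for Lrat and 0.97 for Car3. Infected WT arrays had SDs of 0.15, 0.31 and 0.93 for these genes. In Nrf2 null lungs 8248 genes passed, 3225 higher and 5023 lower, and 1354 of them changed at least 2-fold.

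Markers of recruited leukocytes rose in both genotypes. Of the 155 tests of 31 fixed lists in 5 comparisons, 73 passed with camera's preset correlation and 2 of these with an estimated correlation, both for NRF2 targets between genotypes. Every other group call below rests on the preset value. Of 18 neutrophil markers, 17 rose in each genotype, led in WT lungs by the decoy receptor gene Il1r2 (4.46 ± 0.22) and Slfn4 (4.43 ± 0.32), and G0s2 fell in WT lungs by 0.66. Their median change was 2.19 in WT (camera adjusted p = 1.32e-15, and adjusted p = 0.0974 with an estimated correlation) and 2.47 in Nrf2 null lungs (6.71e-19, and adjusted p = 0.0926 with an estimated correlation). Of 13 neutrophil granule proteins, 8 rose and 1 fell in WT lungs and 7 rose in Nrf2 null lungs, with Mmp9 and Mmp8 highest in WT (1.92 and 1.90; camera adjusted p = 0.000345 and 3.64e-05, and adjusted p = 0.0974 and 0.0924 with an estimated correlation). All 6 NADPH oxidase genes, whose products make the oxidative burst, rose in both, Ncf1 by 2.40 ± 0.14 in WT (1.97e-07 and 9.47e-08, and adjusted p = 0.143 and 0.13 with an estimated correlation). Of 12 monocyte and recruited macrophage markers, 11 rose in WT and 10 in Nrf2 null lungs, led by Arg1 (3.25 ± 0.15 in WT; 2.79e-10 and 2.08e-10, and adjusted p = 0.0718 with an estimated correlation in each). T cell markers rose for 12 of 14 genes in WT, led by Il7r (1.65 ± 0.15), and for 10 in Nrf2 null lungs (11 adjusted over the list alone), where Lef1 fell by 0.61 (2.78e-06 and 0.000152, and adjusted p = 0.443 and 0.567 with an estimated correlation). NK cell markers rose for 7 of 8 genes in WT (8 adjusted over the list alone) and for 5 in Nrf2 null lungs, led by the granzyme gene Gzmb (2.44 ± 0.28 in WT; 0.000259 and 0.000815, and adjusted p = 0.388 and 0.43 with an estimated correlation). The B cell markers did not pass as a group (0.736 and 0.312): only Fcer2a rose in WT, by 1.88 ± 0.22, with a list median of -0.06 against a mean of 0.08 and a test pointing up. In Nrf2 null lungs Fcer2a rose and 4 B cell markers fell (5 adjusted over the list alone). The 16 alveolar macrophage markers did not pass as a group either (0.216 and 0.847), with Itgax higher by 1.26 ± 0.11 and Fabp1 and Siglecf lower by -1.21 ± 0.19 and -1.06 ± 0.18 in WT lungs. There 3 rose and 6 fell (8 adjusted over the list alone), and in Nrf2 null lungs 3 rose and 5 fell (4 and 6 adjusted over the list alone).

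Signalling and antimicrobial groups rose almost completely. Of 22 cytokines and chemokines, 21 rose in each genotype, with medians of 3.90 in WT and 4.35 in Nrf2 null lungs, and the epithelial alarmin gene Il33 fell in WT by 0.51 (camera adjusted p = 1.16e-16 and 3.09e-19, and adjusted p = 0.0974 and 0.0926 with an estimated correlation). All 18 type I interferon response genes rose in both, led by Oasl1 (4.09 ± 0.27 in WT; 8.23e-20 and 9.63e-21, and adjusted p = 0.114 and 0.103 with an estimated correlation). All 14 interferon gamma response genes rose in both, among them the guanylate-binding protein gene Gbp5 by 4.09 ± 0.26 in WT (2.74e-16 and 1.67e-17, and adjusted p = 0.0974 with an estimated correlation in each). Of 20 acute phase and antimicrobial secretion genes, 19 rose in both, with Saa3 up by 3.84 ± 0.62 in WT and the near-identical Saa1 and Saa2, whose probes cannot be told apart with certainty, by 4.37 and 4.49 (5.07e-18 and 8.23e-20, and adjusted p = 0.06 and 0.0539 with an estimated correlation). All 20 pattern recognition and NF-kB feedback genes rose in both, led by Nlrp3 (3.81 ± 0.23) and Tnfaip3 (2.86 ± 0.16) in WT (3.09e-19 and 2.74e-21, and adjusted p = 0.0974 with an estimated correlation in each). Of 15 glycolysis and hypoxia genes, 10 rose and Bnip3 fell in WT, and 9 rose in Nrf2 null lungs (10 adjusted over the list alone), with Hk3 up by 3.47 ± 0.18 and Adm by 3.02 ± 0.23 in WT (0.000105 and 1.15e-05, and adjusted p = 0.0974 and 0.0926 with an estimated correlation). Cell cycle genes rose for 7 of 21 and fell for Bub1 in WT, with Mki67 at 0.99 ± 0.20 (0.0216, and adjusted p = 0.768 with an estimated correlation), and rose for 5 in Nrf2 null lungs (3 adjusted over the list alone; group adjusted p = 0.127). Unfolded protein and integrated stress response genes rose for 2 of 12 in WT (0.205) and for 8 in Nrf2 null lungs, where Atf3 rose 2.84-fold (list 0.00391, and adjusted p = 0.598 with an estimated correlation).

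Markers of the resident lung cells mostly fell. The values come from whole lung RNA, so fewer cells, lower expression and a smaller share of the RNA cannot be told apart. Of 10 alveolar type 1 markers, 9 fell and Pdpn rose in both genotypes, with Igfbp2 and Sema3e lower by -1.14 ± 0.25 and -1.09 ± 0.12 in WT (camera adjusted p = 0.000745 and 0.00103, and adjusted p = 0.43 and 0.443 with an estimated correlation). Of 12 alveolar type 2 markers, 8 fell and the surfactant protein gene Sftpd rose in both (9 fell in WT adjusted over the list alone), led by Hc at -1.78 ± 0.20 and Etv5 at -1.15 ± 0.20 in WT (0.00498 and 0.00493, and adjusted p = 0.668 with an estimated correlation in each). All 8 club cell markers fell in WT, with Cckar at -1.45 ± 0.23 and Cyp2f2 at -1.16 ± 0.22 (0.00122, and adjusted p = 0.457 with an estimated correlation). In Nrf2 null lungs 3 of the 8 club cell markers fell and the group did not pass (0.166). Ciliated cell markers fell for 11 of 11 in WT, led by Dynlrb2 at -1.28 ± 0.11, and for 9 in Nrf2 null lungs (10 adjusted over the list alone; 9.87e-06 and 0.000452, and adjusted p = 0.353 and 0.457 with an estimated correlation). Endothelial markers fell for 12 of 14 in both genotypes (13 in Nrf2 null lungs adjusted over the list alone), with Tek at -0.95 ± 0.13 and Ednrb at -0.93 ± 0.15 in WT (0.000454 and 0.000156, and adjusted p = 0.35 and 0.288 with an estimated correlation). Fibroblast and matrix genes split, 4 up and 5 down in WT and 2 up and 6 down in Nrf2 null lungs (7 down adjusted over the list alone), with Itga8 at -2.23 ± 0.32 and Inmt at -1.41 ± 0.26 in WT (0.855 and 0.206). Markers of other tissues moved too: 5 of 6 cardiac muscle markers fell in both (6 in WT adjusted over the list alone), Myh6 by 1.10 in WT (0.00567 and 0.0115, and adjusted p = 0.457 and 0.502 with an estimated correlation). Of 8 adipocyte markers, 5 fell and 1 rose in WT and 4 fell in Nrf2 null lungs (6 fell in each adjusted over the list alone; 0.285 and 0.125).

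Metabolic and timing groups completed the fixed lists. Circadian clock genes fell for 10 of 15 and rose for 3 in WT (11 fell adjusted over the list alone), with Dbp, Nr1d1, Per3 and Hlf at -3.14, -2.31, -2.26 and -2.25 (camera adjusted p = 0.000356, and adjusted p = 0.181 with an estimated correlation). In Nrf2 null lungs 10 clock genes fell and 1 rose (2 adjusted over the list alone), Nr1d1 by -1.52 and Dbp by -1.30 (0.0283, and adjusted p = 0.457 with an estimated correlation). The hour of death is not given, so a different hour in infected and PBS mice cannot be told apart from a response of clock genes. Xenobiotic metabolism genes outside the NRF2 list fell for 9 of 12 in WT (10 adjusted over the list alone; 0.00956, and adjusted p = 0.66 with an estimated correlation) and for 6 in Nrf2 null lungs (0.148). Within that list Ces1d fell by 1.41 and Cyp1b1 rose by 1.71 in WT. The 31 NRF2 targets went both ways, 7 up and 10 down in WT (11 down adjusted over the list alone; 0.863) and 11 up and 9 down in Nrf2 null lungs (12 up adjusted over the list alone; 0.126). The detoxifying gene Ephx1 fell by 1.16 ± 0.09 and the haem oxygenase gene Hmox1 rose by 1.10 ± 0.10 in WT. Sterol synthesis genes fell for 2 of 14 in WT, Dhcr7 and Insig1 at -0.46 and -0.40, and for 5 in Nrf2 null lungs (0.731 and 0.243). Thymocyte markers rose for 2 of 7 in WT, led by Cd8b1 (0.87 ± 0.21), and for 1 in Nrf2 null lungs (0 adjusted over the list alone in limma, with 2 at unadjusted p under 0.05; group adjusted p = 0.296 and 0.505). Of 4 erythroid markers, limma called 0 in WT (2 at unadjusted p under 0.05) and 1 in Nrf2 null lungs (0 adjusted over the list alone, 3 unadjusted; 0.209 and 0.125). Of 5 sex-linked genes, limma called 0 in either genotype, and 0 had an unadjusted p under 0.05 (0.895 and 0.89, where in Nrf2 null lungs the median was 0.02 and the mean -0.00).

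**Figure D1:**
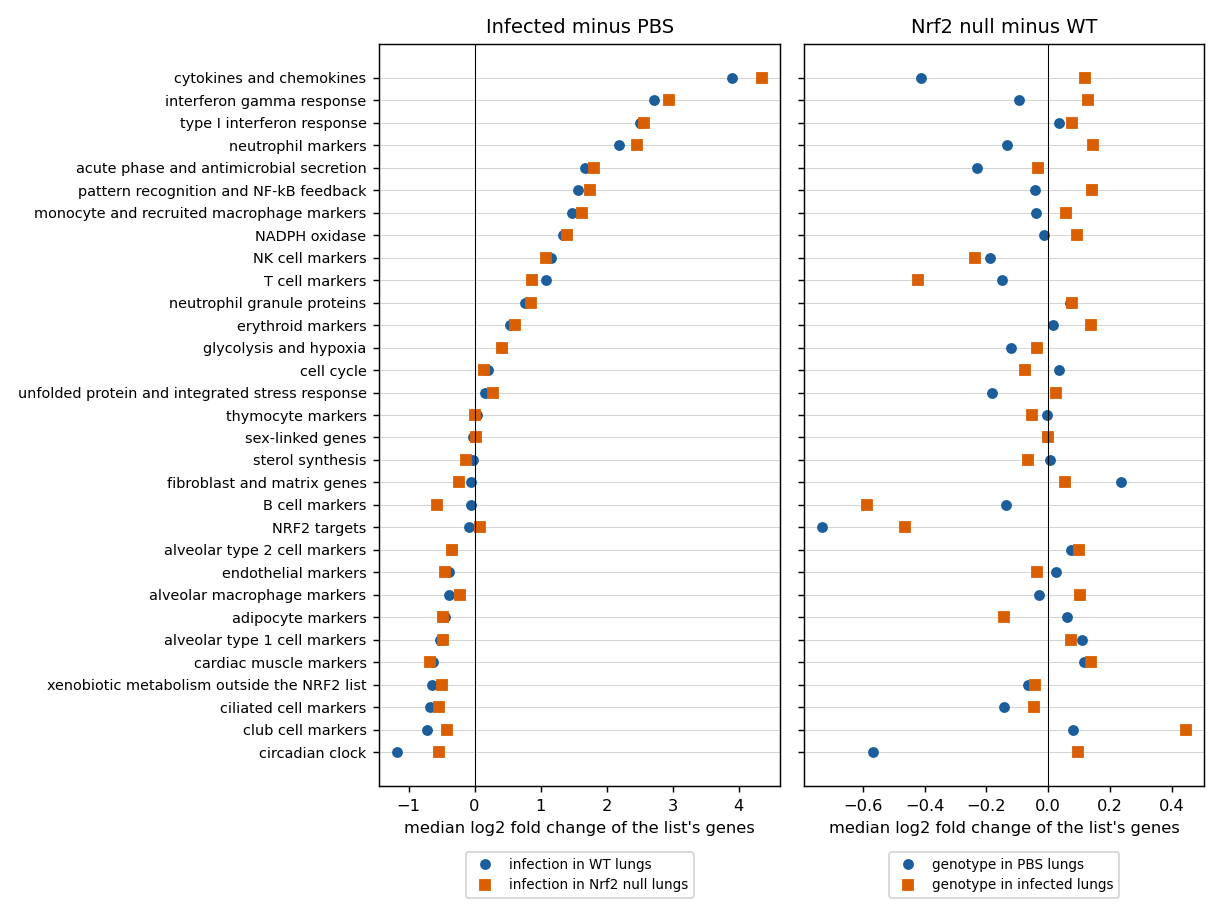
Median log2 fold change of each of the 31 gene lists, for infection against PBS (left) and for Nrf2 null against WT (right), with 1 point per comparison. Cytokines and chemokines rose most with infection in both genotypes (medians 3.90 and 4.35), and NRF2 targets fell most between genotypes in PBS lungs (median -0.73).

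Both infection comparisons used different arrays, so their fold changes can be set against each other directly. Across genes, which are not independent replicates, the changes in WT and Nrf2 null lungs correlated with Pearson r = 0.934 (jackknife SE 0.014) and Spearman rho = 0.818, with a slope of 0.983. Among called genes, 2554 were higher in both genotypes, against 512 for independent lists, and 3922 were lower in both, against 1146, while 5 were called in opposite directions.

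**Figure D2:**
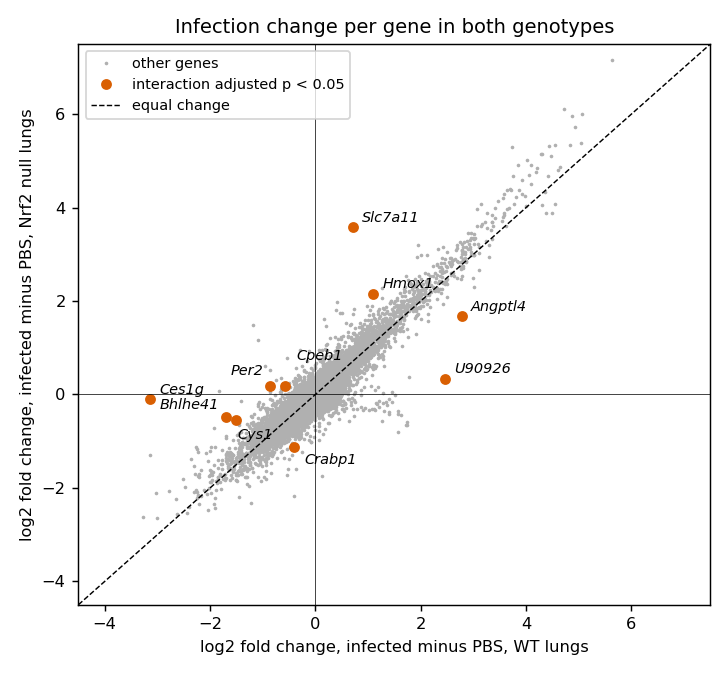
Log2 fold change of each of 21022 genes with infection in WT (x axis) and Nrf2 null lungs (y axis), with the 10 genes past the interaction test in orange and equal change dashed. Most genes lie along the diagonal (r = 0.934), and Ces1g, Slc7a11 and U90926 lie farthest from it among the orange points.

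Whether infection acted differently in the 2 genotypes was tested as the interaction, the change in Nrf2 null lungs minus the change in WT lungs. Ces1g gave 3.04 ± 0.14 (log2 difference of changes ± SE, n = 4 arrays in each group, limma adjusted p = 1.82e-08). It fell from 7.78 to 4.65 in WT lungs and lay at 4.10 and 4.01 in Nrf2 null lungs, below the lower quartile of every array (4.32 to 4.42), where a further fall could not be told from no signal. Its interaction therefore follows from the low level in Nrf2 null lungs and does not show a different response. Slc7a11, the cystine importer gene, gave 2.86 ± 0.27 (0.000154), since infection raised it from 7.19 to 10.78 in Nrf2 null lungs and from 11.34 to 12.06 in WT lungs. Hmox1 gave 1.06 ± 0.14 (0.00748), reaching 10.41 in infected Nrf2 null and 10.44 in infected WT lungs from PBS levels of 8.25 and 9.33. The clock genes Per2 and Bhlhe41 gave 1.04 ± 0.14 (0.00748) and 0.97 ± 0.13 (0.00778). Per2 lay at 9.31 in WT and 8.54 in Nrf2 null PBS lungs, and at 8.45 and 8.72 in infected lungs. For Bhlhe41 these levels were 7.82, 6.94, 6.31 and 6.40. The hour of death is not given, so a different hour cannot be told apart from a different response of clock genes. U90926 gave -2.11 ± 0.22 (0.000395) because it rose to 7.24 in infected WT and lay at 5.28 in infected Nrf2 null lungs. Cys1 gave 1.21 ± 0.19 (0.0214), the lipase inhibitor gene Angptl4 -1.10 ± 0.18 (0.0479) and the retinoid-binding gene Crabp1 -0.72 ± 0.11 (0.0177). Crabp1 lay at 4.38 in WT PBS and at 3.96 and 4.01 in infected WT and Nrf2 null lungs, levels not shown to be above background, so a larger fall in WT lungs could not be seen. Cpeb1, outside the naming rule and chosen after its values were seen, gave 0.76 (0.0206). In all, 10 genes passed, 7 positive and 3 negative, and 1594 had an unadjusted p under 0.05. The count was 68 without infected Nrf2 null replicate 1 (36 positive and 32 negative), 18 without PBS Nrf2 null replicate 3 (12 and 6) and 16 without infected WT replicate 4 (8 and 8). It was 6 (5 and 1) without any one of WT PBS replicates 2 and 3, infected WT replicate 2 or infected Nrf2 null replicate 3. Angptl4 lost its call in 11 of the 16 fits that left out 1 array (adjusted p up to 0.101, without infected Nrf2 null replicate 4), Cys1 in 7 (up to 0.0691, without infected Nrf2 null replicate 3) and Crabp1 in 5 (up to 0.0572, without WT PBS replicate 4).

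Among groups, NRF2 targets changed more positively in Nrf2 null lungs, with 2 genes past the interaction test (5 adjusted over the list alone; camera adjusted p = 1.97e-07, and adjusted p = 0.0974 with an estimated correlation). Clock genes did too, with 2 past the test (9 positive and 2 negative adjusted over the list alone, camera adjusted p = 1.73e-08, and adjusted p = 0.069 with an estimated correlation). For these genes a different hour of death cannot be told apart either. For the club cell markers limma called 0 of 8 in the interaction, and 0 adjusted over the list alone, with 2 at an unadjusted p under 0.05, although all 8 were positive (9.11e-05, and adjusted p = 0.353 with an estimated correlation). Neutrophil markers had 0 genes past the limma interaction test, 3 adjusted over the list alone and 4 unadjusted (3.68e-06, and adjusted p = 0.421 with an estimated correlation). The cytokines and chemokines had 0 genes called by limma, 0 adjusted over the list alone and 4 unadjusted (0.000101, and adjusted p = 0.502 with an estimated correlation). Their group means were 9.70 and 9.76 in infected WT and Nrf2 null lungs and 6.44 and 6.00 after PBS, where WT PBS replicate 1 stood apart at 7.11. For cardiac muscle markers (0.839) the median was -0.01 against a mean of 0.04 and a test pointing up.

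The comparison of Nrf2 null with WT lungs after PBS asks what NRF2 maintains without infection. Slc7a11 fell by 4.15 ± 0.19 (log2 fold change ± SE, n = 4 arrays per group, limma adjusted p = 2.44e-09), a 17.8-fold difference. Ces1g fell by 3.68 ± 0.10 (5.38e-12), to 4.10, a level not shown to be above background, so the size of its change is uncertain. It was -3.43 with values under each array's lower quartile raised to it. H60c, a ligand gene of the receptor NKG2D, fell by 2.89 ± 0.12. Nqo1 fell by 2.18 ± 0.10 and the carbonyl reductase gene Cbr3 by 2.05 ± 0.21. Sectm1b fell by 1.90 ± 0.25 and the lymphocyte checkpoint receptor gene Tigit by 1.84 ± 0.25. The glutathione transferase gene Gsta1 fell by 2.19 ± 0.23, uncertain because near-identical copies share its probes. The rises were smaller: the clock activators Npas2 and Arntl rose by 1.45 ± 0.21 and 1.30 ± 0.18 (0.00176 and 0.000966). Angptl4 rose by 1.04 ± 0.13 (0.000396), Lrrc17 by 0.94 ± 0.13 and the protease gene Adamts12 by 0.87 ± 0.12. Jchain, the joining chain of secreted antibodies, rose by 1.08 ± 0.24 (0.0436), Spon2 by 0.90 ± 0.20 (0.0366) and the neuropeptide gene Gal by 0.88 ± 0.18 (0.0245). In all, 225 genes passed, 64 higher and 161 lower, 46 of them by at least 2-fold, and the count was 144, 140 and 143 without WT PBS replicates 1, 2 and 3. Leaving out 1 array ended the call of Jchain in 12 of 16 fits (adjusted p up to 0.152, without PBS Nrf2 null replicate 2), Spon2 in 8 (0.135, without WT PBS replicate 1) and Gal in 5 (0.0937, without WT PBS replicate 3).

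NRF2 targets carried the clearest group change in PBS lungs: 24 of 31 fell (29 adjusted over the list alone), with a median of -0.73 (camera adjusted p = 2.08e-70, and adjusted p = 9.54e-05 with an estimated correlation). Besides the genes above, the sulfiredoxin gene Srxn1 fell by 1.67 ± 0.13. Of 15 circadian clock genes, 6 fell and 2 rose (11 fell adjusted over the list alone), with Dbp and Bhlhe41 at -1.52 ± 0.32 and -0.88 ± 0.09 opposite to Npas2 and Arntl (3.09e-09, and adjusted p = 0.06 with an estimated correlation). Dbp lost its call in 6 fits that left out 1 array (up to 0.0887, without WT PBS replicate 1). Cytokine and chemokine genes lay lower as a group, with a median of -0.41 (5.00e-05, and adjusted p = 0.477 with an estimated correlation). Only Il6 passed, at -1.60, and it lost its call in 7 such fits (up to 0.106, without PBS Nrf2 null replicate 2). WT PBS replicate 1 had a mean of 7.11 over these 22 genes, against 6.09 to 6.34 in the other WT PBS arrays and 5.89 to 6.06 in the Nrf2 null PBS arrays. Neutrophil markers lay lower with Clec4e, Cd177 and Clec4d past the test, the latter at -1.12 and -0.84 (0.000101, and adjusted p = 0.495 with an estimated correlation). Their mean was 7.99 and 8.14 in WT PBS replicates 1 and 3, but 7.57 and 7.67 in replicates 2 and 4, within the Nrf2 null PBS range of 7.49 to 7.68. Clec4d lost its call in 9 of the fits (up to 0.137, without WT PBS replicate 1). Fibroblast and matrix genes lay higher, with the fibrillin gene Fbn1 past the test at 0.41 (5 adjusted over the list alone; 7.98e-06, and adjusted p = 0.318 with an estimated correlation). The detoxifying gene Aldh3a1 fell by 1.67 and was the only one of 12 xenobiotic metabolism genes past the test (0.03, and adjusted p = 0.71 with an estimated correlation). Acute phase genes lay lower as a group (0.00163, and adjusted p = 0.457 with an estimated correlation), but WT PBS replicate 1 had a mean of 9.32 over them, against 8.76 to 8.88 in the other WT PBS arrays and 8.56 to 8.90 in the Nrf2 null PBS arrays. The lactoferrin gene Ltf rose by 0.56 (4 fell and 1 rose adjusted over the list alone), a call lost in 10 of the fits (up to 0.145, without PBS Nrf2 null replicate 2).

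In 6 further groups of the PBS comparison limma called 0 genes and the lists shifted only with the preset correlation. Unfolded protein and integrated stress response genes lay lower for 12 of 12, with 0 called adjusted over the list alone and 4 at unadjusted p under 0.05 (median -0.18, camera adjusted p = 4.06e-05, and adjusted p = 0.409 with an estimated correlation). T cell, ciliated cell and glycolysis lists lay lower (0.00608, 0.0056 and 0.0107), with adjusted p = 0.71, 0.612 and 0.353 with an estimated correlation and 1, 3 and 5 genes unadjusted. PBS Nrf2 null replicate 1 had the lowest T cell mean (6.51, against 6.95 to 7.19 in the other 3) and replicate 2 the lowest unfolded protein response mean (8.98, against 9.30 to 9.60). Adjusted over the list alone, 2 glycolysis genes fell and 0 of the T cell or ciliated cell markers did. Alveolar type 2 and type 1 markers lay higher (0.0144 and 0.0386, and adjusted p = 0.71 and 0.698 with an estimated correlation), with 2 and 4 genes unadjusted and 0 adjusted over the list alone. For type I interferon response genes, whose group did not pass (0.827), the median was 0.04, the mean -0.03 and the test pointed down. The same mismatch held for NADPH oxidase genes (0.834), with a median of -0.01, a mean of 0.01 and a test pointing up, and for thymocyte markers (0.686), with a median and mean below 0 and a test pointing up.

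**Figure D3:**
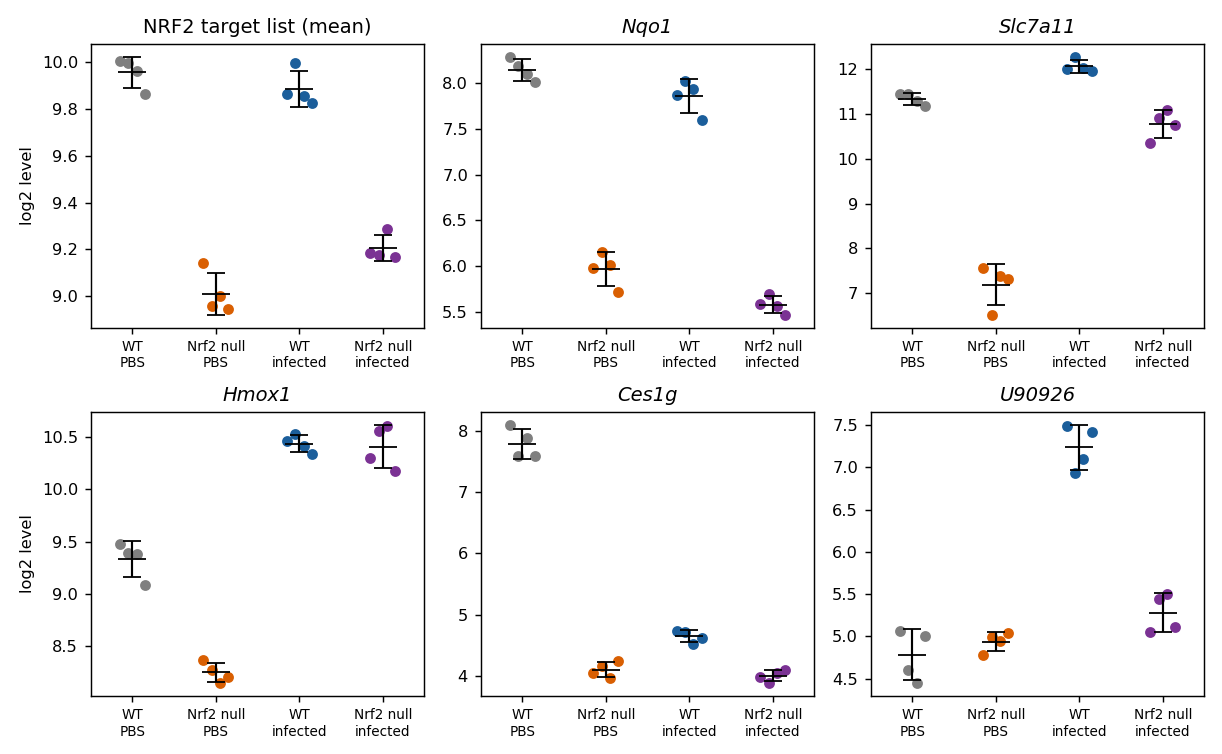
Mean log2 level of the 31 NRF2 targets on each array (first panel), by group, with group mean and SD as bars. The other panels show the log2 levels of Nqo1, Slc7a11, Hmox1, Ces1g and U90926. In the first panel, the lowest WT array lay 0.72 above the highest Nrf2 null array after PBS and 0.54 above it after infection.

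**Figure D4:**
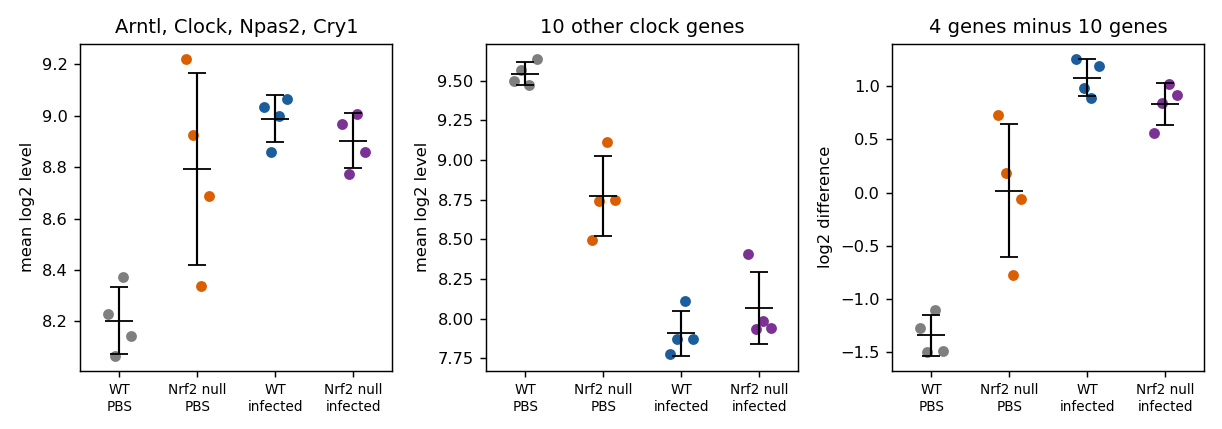
Mean log2 level on each array of Arntl, Clock, Npas2 and Cry1 (left), of Dbp, Tef, Hlf, Per1, Per2, Per3, Nr1d1, Nr1d2, Ciart and Bhlhe41 (middle), and the difference of both means (right), with group mean and SD as bars. After PBS the WT mean of the difference was -1.34 and the Nrf2 null mean 0.02, and after infection the 2 genotypes differed by -0.24.

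The comparison of Nrf2 null with WT lungs after infection asks which of these differences hold during pneumonia. H60c fell by 2.29 ± 0.12 (n = 4 arrays per group, limma adjusted p = 4.04e-08), Nqo1 by 2.28 ± 0.10 (4.15e-09). Cbr3 fell as well (0.000119), and U90926 fell by 1.96 ± 0.15 (4.75e-06). The glutathione transferase gene Gsta3 fell by 1.60 ± 0.28 (0.0108) and Srxn1 by 1.53 ± 0.13 (1.35e-05). Gsta1 fell by 1.89 ± 0.23 and Mup10, a major urinary protein gene, by 1.78 ± 0.21, both uncertain because near-identical copies share their probes. Jchain rose by 2.02 ± 0.24 (0.000527), 4.07-fold, and was the only gene higher by at least 2-fold. Ltf rose by 0.80 ± 0.12 (0.00512) and the tight junction gene Cldn1 by 0.77 ± 0.13 (0.00824). The pseudogenes Pisd-ps3 and Tmem181b-ps rose by 0.97 ± 0.13 and 0.75 ± 0.09, uncertain because they resemble their parent genes. Asb14, Dedd2 and the defensin gene Defb25 rose by 0.61, 0.55 and 0.51. These calls were lost in 11, 13 and 5 of the 16 fits that left out 1 array (adjusted p up to 0.112 without infected WT replicate 4, 0.138 without infected WT replicate 3 and 0.0893 without infected Nrf2 null replicate 3). In all, 111 genes passed, 15 higher and 96 lower, 23 of them by at least 2-fold, and the count was 70 without infected WT replicate 2 (13 higher and 57 lower) and 200 without infected Nrf2 null replicate 1 (66 and 134). It was 127 without infected Nrf2 null replicates 1 and 2 (40 and 87), a fit chosen after seeing the data. With only the 8 arrays compared, Ltf, Cldn1 and Gsta3 gave adjusted p = 0.0857, 0.107 and 0.178.

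NRF2 targets fell as a group during infection as well: 16 of 31 fell (25 adjusted over the list alone), with a median of -0.46 (camera adjusted p = 1.12e-43, and adjusted p = 0.000587 with an estimated correlation). B and T cell markers lay lower without single genes passing, and NK cell markers did not pass as a group (median -0.24, 0.0638). With the replicate number as a block NK cell (0.0371), alveolar type 1 (0.0477) and interferon gamma response lists (0.0312) passed at the preset correlation, the last 2 higher and at 0.0629 and 0.0502 without the block. None of these lists passed with an estimated correlation without the block. For the B cell list limma called 0 of 12, with 8 at unadjusted p under 0.05, while 7 fell adjusted over the list alone, led by the kinase gene Blk (-1.07) and Cd79a (-0.94). The median was -0.59 (1.15e-06, and adjusted p = 0.43 with an estimated correlation). For the T cell list limma called 0 of 14, with 9 unadjusted, while 7 fell adjusted over the list alone, led by Lef1 and Cd3e (each -0.56). Their median was -0.42 (1.34e-07, and adjusted p = 0.388 with an estimated correlation). Club cell markers lay higher, with 0 of 8 called by limma, 6 unadjusted and 6 rising adjusted over the list alone, led by Cckar (0.77) and Cyp2f2 (0.76), and their median was 0.45 (1.18e-06, and adjusted p = 0.2 with an estimated correlation). Neutrophil granule proteins lay higher with Ltf past the test (2 adjusted over the list alone; 0.0326, and adjusted p = 0.39 with an estimated correlation). Pattern recognition genes and alveolar type 2 markers lay higher with 0 genes called by limma, 0 adjusted over the list alone, and 2 and 0 unadjusted (0.00103 and 0.0326, and adjusted p = 0.668 and 0.744 with an estimated correlation). Aldh3a1 fell by 1.14 in a xenobiotic metabolism list that did not pass (0.863, with a median of -0.04, a mean of 0.06 and a test pointing down). Signs differed also for glycolysis genes (0.855, median -0.04 against a mean of 0.01, test down), unfolded protein response genes (0.863, 0.03 against -0.05, test down) and sex-linked genes (0.779, -0.00 against 0.01, test up). The nuclear receptor gene Pparg fell by 0.52 among alveolar macrophage markers, a call lost in 12 fits that left out 1 array (up to 0.108, without infected WT replicate 3). Of these 16 markers 13 changed positively, 2 rose and 2 fell adjusted over the list alone, and the group did not pass (camera adjusted p = 0.185). Of 22 cytokines and chemokines limma called 0 between the infected genotypes, 0 adjusted over the list alone and 1 unadjusted (0.367), and of 15 clock genes 0, 0 and 2 (0.291).

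The genotype comparisons after PBS and after infection, which share no arrays, correlated across genes with r = 0.242 (jackknife SE 0.141; 0.121 without infected Nrf2 null replicate 1) and rho = 0.099. Among called genes, 57 were lower in both, against 0.7 for independent lists, and 5 were higher in both, against 0. These 5, named after their values were seen, were Jchain, Ltf, Tbc1d8, Pisd-ps3 and Tmem181b-ps.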

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

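Of the tests in this part, those of a mislabelled array, the hour of death, cell makeup and every test of the spread among infected Nrf2 null arrays were chosen only after the result was seen, and the criterion for other tissue was also rewritten after its first run.

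The first pattern is the set of genes called between genotypes. DNA of the targeted strain carried along beside Nfe2l2 is not the source of most of them: 0.365% of the 274 called genes lie within 20 Mb of Nfe2l2 (1 gene, Mir130a; 95% interval 0.00924% to 2.02%), where 1.96% of all genes lie. Whether such DNA is the source of some calls cannot be told apart, since only 1 called gene lies there and the interval of the odds ratio of 0.181 runs from 0.00457 to 1.02 (Fisher's exact p = 0.0477). A mislabelled array is argued against by the NRF2 targets, whose lowest WT array lay at least 0.54 above the highest Nrf2 null array given the same instillate, while the largest SD within a group was 0.09. Loss of NRF2, the biological difference in the design, predicts a fall of its targets. Of the 31 listed targets, 24 fell after PBS and 16 after infection, and 0 rose in either. For called genes outside that list, loss of NRF2 stays open as an untested candidate explanation. Differences in housing or litter, which the labels do not give, stay open for all of the calls.

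The second pattern is a shift among clock genes in PBS lungs of Arntl, Npas2, Clock and the repressor Cry1 against Dbp, Tef, Hlf, Per1, Per2, Per3, Nr1d1, Nr1d2, Ciart and Bhlhe41, led among the first 4 by Npas2 and Arntl, while Clock changed by 0.10 and Cry1 by -0.49. The difference between both means shifted by 1.36 from WT (mean -1.34, SD 0.19, n = 4) to Nrf2 null (0.02, SD 0.62, n = 4; exact permutation p = 0.0286, the smallest that 4 against 4 arrays can give), and by -0.24 after infection (exact permutation p = 0.143). A single array is not the source, since the shift was at least 1.12 when any 1 of the 8 arrays was left out. A change in cell makeup cannot be told apart: 6 of 16 cell type lists were called, 3 up and 3 down, and 0 with an estimated correlation. A different hour of death cannot be told apart from an effect of Nrf2 on the clock: the hour is not given, and the shift of 1.36 is the pattern itself, so it tests neither.

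The third pattern is the spread among infected Nrf2 null arrays on the first principal component, 20.45 for replicate 1 and 57.79 for replicate 2 against 38.01 and 45.09. Random noise of single arrays cannot be told apart from a different extent of the infection response. Each array's deviation correlated across genes with the WT infection change at -0.546 for replicate 1 and 0.569 for replicate 2 (at least 0.546 in size), but both arrays were picked at opposite ends of this component, which separates infected from PBS lungs, so large correlations of opposite sign were fixed in advance. Other tissue taken with the lung cannot be told apart: cardiac muscle markers of replicate 1 (10.38) lay 1.69 SD above the range of 6 other infected arrays (9.65 to 10.12), but below the PBS mean of 10.63, and infection itself lowers them. As first written, the criterion took distances in either direction and gave 3.55 SD, from thymocyte markers below the others in replicate 1 (4.78 against 4.94 to 5.09), and it was restricted to values above because added tissue can only add RNA.

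Other splits of the arrays were used to ask whether chance gives as many calls. In each comparison of 2 groups, 1 of the 35 splits, the real one, called as many genes, a share under 0.05. The counts were 8134 against at most 1 for infection in WT lungs and 8248 against 3 in Nrf2 null lungs. They were 225 against 0 for genotype after PBS and 111 against 87 after infection. Other splits mix the 2 groups compared, infected with PBS arrays or WT with Nrf2 null arrays. For genes that differ between these groups, mixing widens the spread within groups and lowers the counts of the other splits. The real split is favoured by this in each comparison of 2 groups. For genotype after infection the margin is narrow, so chance is not excluded there. The real count was 70 without infected WT replicate 2 and 41 with only the 8 arrays compared, fits for which no other splits were run. For the interaction, 4 of 100 assignments of genotype within each instillate, the real one included, called as many as the real 10 genes. The highest other called 331 genes, which points to a structure of the samples, but what produced these calls was not tested.

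Single arrays far from the other 3 of their group were found in 4 of 124 group values of lists, 12 of 216 of named genes and 1 of 8 of principal components, and chance gives about 1 in 20 groups. Infected Nrf2 null replicate 3 had an NRF2 target mean of 9.29 (others 9.17 to 9.19), replicate 4 an NK cell marker mean of 7.94 (7.1 to 7.2), and replicate 1 an erythroid mean of 9.27 (8.5 to 8.63), Adamts12 at 6.62 (6.21 to 6.24) and Srxn1 at 8.09 (8.18 to 8.2), while replicate 2 had Fgfr4 at 5.47 (6.97 to 7.05). Infected WT replicate 2 had neutrophil granule proteins at 8.13 (8.23 to 8.24), Abca8a at 7.11 (7.42 to 7.45) and Arntl at 8.77 (9.03 to 9.07). WT PBS arrays held 5 of the 12 gene values: Acod1 9.05 (5.27 to 5.78), Cxcl10 9.16 (6.35 to 6.62) and Orm2 6.94 (5.46 to 5.53) in replicate 1, and Tigit 7.59 (8.13 to 8.22) and Pisd-ps3 9.89 (10.41 to 10.48) in replicate 4. PBS Nrf2 null replicate 1 had Abca8a at 10.35 (9.96 to 10), replicate 4 had H60c at 5.59 (5.11 to 5.17), and replicate 2 lay at -17.42 on the second component (-7.67 to -7.09).

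The infection response differed between genotypes, by limma's interaction test, for Ces1g (3.04), Slc7a11 (2.86), Cys1 (1.21), Hmox1 (1.06), Per2 (1.04), Bhlhe41 (0.97), Cpeb1 (0.76), Crabp1 (-0.72), Angptl4 (-1.10) and U90926 (-2.11), but Ces1g in Nrf2 null lungs and Crabp1 in infected lungs lay too low for a further fall to be seen. For the clock genes Per2 and Bhlhe41 a different hour of death cannot be told apart from a different response. With camera's preset correlation 13 lists differed, and 0 of them with an estimated correlation. Their median differences were 0.62 for circadian clock, 0.14 for NRF2 targets, 0.36 for neutrophil markers, 0.36 for club cell markers, 0.56 for cytokines and chemokines, 0.17 for pattern recognition and 0.18 for unfolded protein response genes. They were -0.48 for B cell markers, -0.20 for fibroblast and matrix genes, 0.15 for acute phase genes, 0.25 for interferon gamma response genes, 0.11 for ciliated cell markers and -0.24 for T cell markers.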

How the results depend on the processing

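The setting without infected Nrf2 null replicates 1 and 2 was chosen after seeing the data, and all others were planned. No correlation reversed sign. Among the lists and the 665 named gene and comparison pairs, none called in the main setting or an alternative reversed direction between them. Lists and pairs called in neither, and all other genes, were not compared for direction. Where a count moved for another reason than a stricter rule or fewer arrays, the cause was not tested. Requiring a 2-fold change, a stricter rule, left 1316 and 1354 genes for infection in WT and Nrf2 null lungs and 46 and 23 for genotype after PBS and infection. Adjusted p under 0.01 left 114, 58 and 6 genes for genotype after PBS, after infection and the interaction, and unmoderated variances left 6 in the interaction. Array weights gave 397 for genotype after PBS and 35 for the interaction. Leaving out infected Nrf2 null replicates 1 and 2 gave 348 and 18, and a fit of only the 8 arrays compared gave 41 for genotype after infection. Leaving out each array gave 7306 to 8433 and 7273 to 8577 for infection, 140 to 297 and 70 to 200 for genotype and 6 to 68 for the interaction, with correlations of 0.923 to 0.938 and 0.121 to 0.286 and Nfe2l2 at -0.09 to -0.05 and -0.13 to -0.08. Infected Nrf2 null replicate 1 gave the highest value of each count. The correlation of infection changes was 0.964 without the genes of below-median level and 0.818 as Spearman rho, and that of genotype changes 0.376 and 0.099. With the replicate number as a block, counts were 7988, 8110, 201, 84 and 11. Whether the numbers pair the samples cannot be told from correlations between arrays of different groups, taken after each gene's group mean was subtracted. So measured, the 24 pairs of the same number correlated at -0.107 to 0.207 (median 0.025). The 72 pairs of different number correlated at -0.2 to 0.224 (median -0.01). Of 16 arrays, 6 correlated best with their own number, a hint from the data only. The calls of NRF2 targets between genotypes held in every alternative of the list tests, while 71 other list calls were lost with an estimated correlation. Of 282 calls among the named gene and comparison pairs, 191 held in every alternative and 261 in every fit without 1 array. Among the 10328 transcripts outside the main test, 1984, 1950, 59, 52 and 3 were called, and without the genes within 20 Mb of Nfe2l2, 224 and 111 genes were called between genotypes. No background values were given, so what signal over background limits among dim genes was not measured. A covariate for Y-linked genes was not run because the arrays did not differ in them, nor was another Nfe2l2 transcript, since only 1 matched transcript belongs to it.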

Other observations

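The observations in this part were all chosen after their values were seen. Vomeronasal receptor genes of the Vmn1r family were called higher with infection in WT lungs for 22 of 165 members (3339 of 21022 over all genes), and for 1 in Nrf2 null lungs, where 3 were lower. Their mean level was 4.92, 4.99 and 4.80 in infected WT replicates 1, 2 and 3 and 4.64 in replicate 4, against 4.59 to 4.65 in WT PBS lungs, and 4.85 in infected Nrf2 null replicate 1 against 4.61 to 4.65 in the other infected Nrf2 null arrays. In Nrf2 null PBS lungs it was 4.64 in replicate 1 and 4.81 to 4.86 in the other 3, so arrays of every group but WT PBS were among the raised ones. The source of the spread was not tested.

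Of 10 major urinary protein (Mup) genes, 4 rose with infection in WT lungs and limma called 0 in Nrf2 null lungs, with 4 lower in infected Nrf2 null than infected WT lungs and 0 past the interaction test. Their mean was 5.08 to 5.43 on infected WT arrays. On infected Nrf2 null arrays it was 4.83 in replicate 1 and 4.57 to 4.62 in the others. All these means lie below the lowest array median of 5.63. Near-identical copies share probes, so the members are not independent, and the source of the difference was not tested. The inducible heat shock genes Hspa1a and Hspa1b rose with infection in Nrf2 null lungs by 1.48 and 1.16 (limma adjusted p = 0.0172 and 0.049). They are near-identical copies whose probes cannot be told apart with certainty, so they do not count as independent genes. In WT lungs they changed by -1.18 and -1.08 (adjusted p = 0.0533 and 0.0663), and neither passed the interaction test (0.219 and 0.332). Infected Nrf2 null replicate 3 held the highest level of both, 12.69 for Hspa1a.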
